A study of Mus musculus with 12 samples.

How the data were processed

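RNA-seq counts were analysed for 12 libraries of palatal shelf tissue from C57BL/6 mouse embryos at E13.5: anterior and posterior palate from control and from tamoxifen-treated embryos, 3 libraries per group. The files deposited by the authors hold one raw count per gene symbol and library, 24391 symbols each, without normalization. Per the submitters' processing notes, HISAT2 and StringTie were used with genome build mm9. Their versions, the counting program, the annotation and the strand setting are not given in the sources used here. Among counts of 1 to 100 the share of even values was 57.1 to 60.1% per library, so the 2 mates of a read pair appear to have been counted separately. The labels do not state whether replicates are separate animals or litters, so the p-values measure the spread between these samples. Dose and time of the tamoxifen treatment and any batch are not given in the sample labels. Total counts ranged from 39.4 M to 73.0 M per library.

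Tests used R 4.3.3 with edgeR 4.0.16: filterByExpr by group left 15958 genes, TMM scaling was applied, and a robust quasi-likelihood fit with 1 mean per group over all 12 libraries (8 residual degrees of freedom) gave 5 contrasts. These were tamoxifen against control in each part of the palate, the difference of these effects (interaction), and anterior against posterior palate in controls and under tamoxifen. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Fold changes are on the log2 scale or as ratios, levels are TMM-scaled CPM, and errors are SD over 3 libraries or the standard error (SE) of the fold change. A comparison of 3 against 3 values cannot give an exact p under 0.1, so levels are given without a test of their own.

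Before the data were examined, 38 gene lists (pathways and cell type markers) were fixed. Of these, 37 had at least 3 tested members and were tested with camera (limma 3.58.1, prior count 2) with an estimated correlation between genes, with the preset correlation of 0.01 and fry as alternatives. For each list the called members were counted over all genes tested and adjusted over the list alone. Named genes followed a rule fixed at the same time. Among called genes without overlap between the 3 and 3 values and with a group mean of at least 5 CPM, the 6 largest rises and 6 largest falls per contrast could be named, and up to 2 genes per list with the smallest adjusted p. Esr1, Esr2, Pgr and Greb1 were always given for treatment, and Shox2, Msx1, Bmp4, Fgf10, Meox2, Tbx22, Barx1 and Mn1 for region. For the interaction the condition on overlap was dropped, and a list without a call could be represented by its member with the smallest p. Names outside the rule are given as chosen after their values were seen. Some genes that met the rule are not reported here.

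Alternatives fixed at the same time were DESeq2 1.42.0, limma-voom, other scalings, filters and thresholds, an embryo sex covariate from Xist and Y-linked counts, the replicate number as a block, the 6 libraries of a comparison alone, and leaving out each library. Chosen after seeing the data were the removal of a length and GC trend (with and without the block), division of the counts by 2, and thinning of all libraries to the lowest total. Length and GC content came from the longest GENCODE transcript per symbol in a newer mouse genome build than that of the authors, so no coordinates were used. Of the 24391 symbols 23348 matched directly and 670 by an older symbol, which gave 15847 of the tested genes a value. For each library, a surface of natural splines (4 degrees of freedom each for length and GC) was fitted to genes with a mean log2 CPM above 1, and removed as an offset.

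The fits were tested on simulated data built on the anterior tamoxifen comparison with 200 changed genes among 15688. edgeR called 85% of genes changed 1.5-fold and 98% of those changed 2-fold, with 14 unchanged genes called. DESeq2 called 83% and 99% with 33 unchanged genes called, and limma-voom 84% and 97% with 17. The spread of each simulated gene followed the fitted trend with expression level, without a spread of its own. The 200 changed genes were balanced between rises and falls, whereas 49.7% of the genes tested were called in the real comparison. These rates may therefore not hold for the real data. camera called a list planted at 1.4-fold (adjusted p = 2.8e-05) and 0 other lists. The planted genes were those of the cholesterol list, drawn independently of each other, whereas their estimated correlation in the real data was 0.29. The simulation therefore does not measure the power of camera for lists of correlated genes. With a simulated length and GC trend (15633 genes), edgeR called 80% of 1.5-fold and 92% of 2-fold changes and 5975 unchanged genes, and after removal of the trend 76% and 94% with 12 unchanged genes. That trend followed the same length and GC values that its removal used, so errors in these values were not simulated. Of 18 pairs of libraries with the same replicate number in different groups, 2 had a correlation above 0.1, both between the anterior and posterior tamoxifen groups (0.147 and 0.137). Among other groups, 7 of 12 libraries correlated best with their own number, and with only 3 numbers part of such matches would arise by chance. The interferon response pattern described below was also shared by replicate 1 of both tamoxifen groups. Whether the numbers pair the samples is therefore not settled, and the main fit did not treat them as pairs. The deposited files carry other numbers than the sample titles for some libraries. The title numbers were used for this check, for the block and for naming the library left out, and pairing by file number was not tested.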

Results

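RNA was sequenced from the palatal shelves, the paired outgrowths that form the roof of the mouth, of C57BL/6 mouse embryos at E13.5. The shelves had been separated into an anterior and a posterior part, and the embryos came from tamoxifen-treated mice or from controls, which gave 4 groups of 3 libraries. Tamoxifen is a selective oestrogen receptor modulator, and the title of the series names cleft palate as an outcome of the drug. Total counts per library ranged from 39.4 M to 73.0 M, with the second highest at 50.2 M. Of 24391 gene symbols, 15958 passed the expression filter and were tested. Replicates of a group differed by more than counting noise in every pair (chi-square per degree of freedom of 10.3 or more), so no library was treated as a duplicate. Transcripts of Xist (154 to 446 CPM, counts scaled to a common library size) and of Y-linked genes (49.3 to 115 CPM in sum) were both present in every library.

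Region and treatment both separated the libraries. The first principal component of the log2 CPM values held 51.9% of the variance, and its scores ran from -53.8 to -41.1 in the anterior libraries and from 38.3 to 53.4 in the posterior libraries. The next component held 21.3%, with scores of 17.6 to 43.4 in the controls and -43.5 to -14.7 under tamoxifen.

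**Figure D1:**
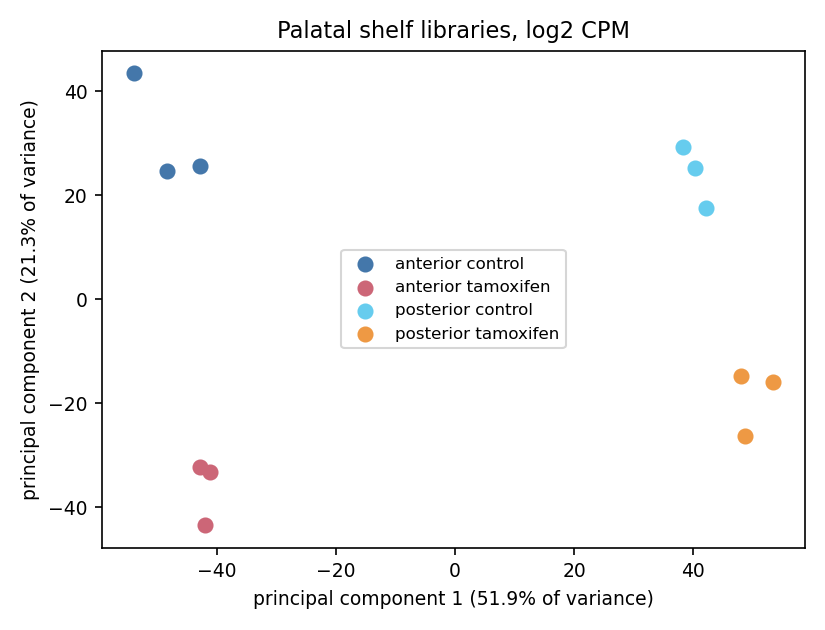
Scores of the 12 libraries on the first (x axis) and second (y axis) principal component of log2 CPM, with 1 point per library coloured by group. Anterior and posterior libraries separate on the x axis (51.9% of the variance), and control and tamoxifen libraries on the y axis (21.3%).

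The regional comparison in controls asked which genes distinguish the anterior from the posterior shelf in normal development. Shox2, a homeobox gene of the anterior palate, stood at 332 ± 27.6 CPM in the anterior and 18.7 ± 1.89 CPM in the posterior shelf (mean ± SD, n = 3), a 17.8-fold difference. Msx1, a homeobox gene needed for palate and tooth development, stood at 493 ± 111 against 16.8 ± 6.14 CPM, 29.2-fold higher anteriorly. The homeobox gene Alx1 was 31.5-fold and Sp5, a target of Wnt signalling, 31.6-fold higher in the anterior shelf. In the opposite direction, Meox2 was 19.3-fold and Tbx22, the gene of X-linked cleft palate, 6.92-fold higher in the posterior shelf. The largest posterior excess in absolute terms among these regional genes belonged to Barx1, with 979 ± 110 CPM posteriorly and 399 ± 39.1 CPM anteriorly, while Mn1 was 1.63-fold higher posteriorly. Fgf10 was 2.27-fold higher in the anterior shelf. Bmp4, at 47.1 ± 5.70 and 43.8 ± 3.54 CPM, gave no call between the parts (log2 fold change 0.11, SE 0.10, adjusted p = 0.48). Counts of Msx1os, an RNA antisense to Msx1, were 19.4-fold higher anteriorly, but the strand of counting is not stated and they cannot be separated from those of Msx1.

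**Figure D2:**
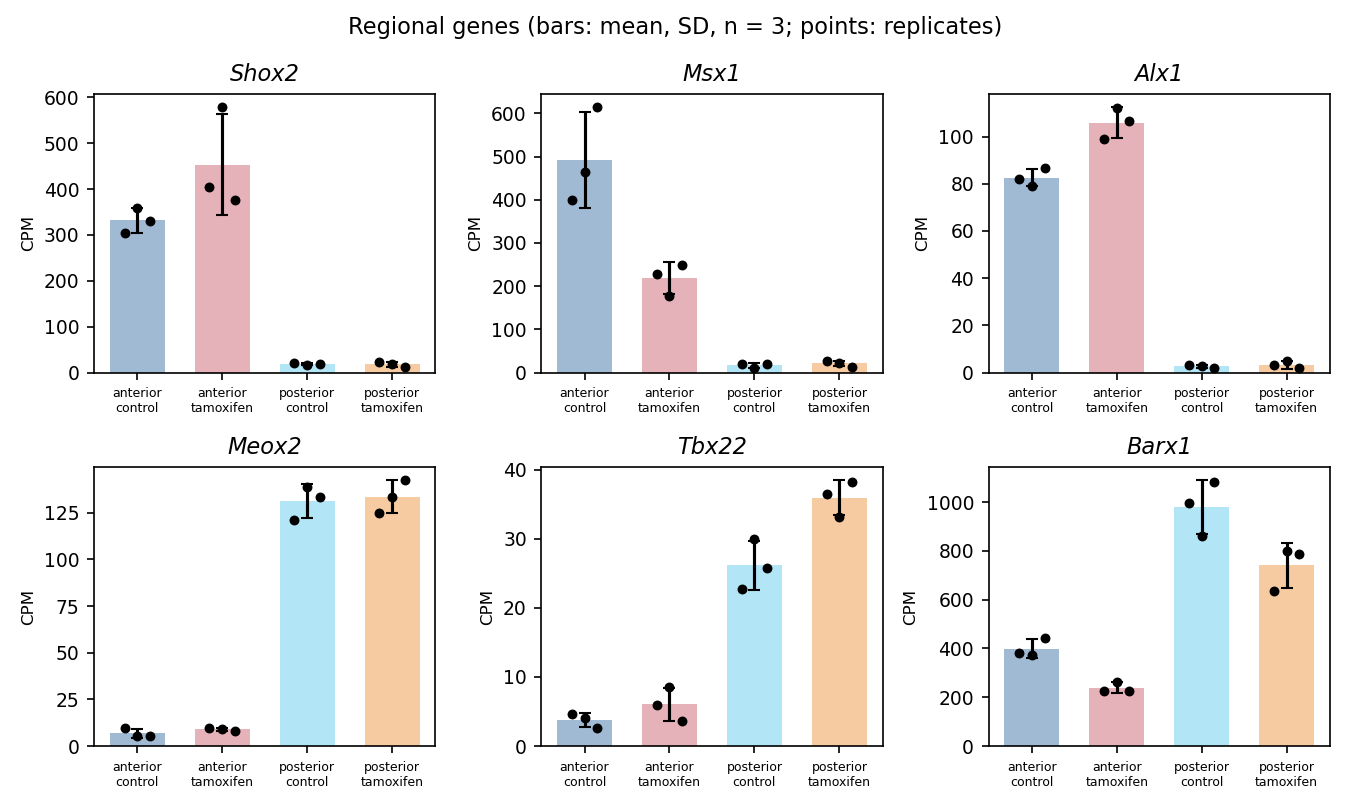
CPM (y axis, from 0) of 6 regional genes in the 4 groups (x axis), with bars for the mean, error bars for the SD over 3 libraries and a point per library. Shox2, Msx1 and Alx1 are high in anterior libraries (332, 493 and 82.7 CPM on average in controls), and Meox2, Tbx22 and Barx1 in posterior libraries (131, 26.2 and 979 CPM).

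Gene groups fixed in advance followed the same division. Of 12 anterior palate genes, 8 were higher and 0 lower in the anterior shelf (adjusted over the list alone, 9 and 1), among them the activin subunit gene Inhba at 3.69-fold. Of 12 posterior palate genes, 0 were higher and 10 lower (adjusted over the list alone, 0 and 12), among them Col25a1 at 5.34-fold higher posteriorly. Both lists passed the camera test with an estimated correlation (adjusted p = 0.012 each), but not with the replicate number as a block (0.060 each). Skeletal muscle genes were lower in the anterior shelf for 22 of 23 members, also when adjusted over the list alone. Tnni1, a slow troponin of muscle fibres, stood at 0.818 ± 0.360 CPM anteriorly and 39.4 ± 4.21 CPM posteriorly, and Tnnt1 at 3.19 ± 0.696 and 58.7 ± 3.72 CPM. Cartilage genes were lower for 14 of 17 members (adjusted over the list alone, 15), with Col2a1 5.13-fold and Col9a3 3.64-fold higher posteriorly. Muscle and cartilage lists passed camera with the preset correlation (adjusted p = 2.7e-23 and 2.2e-11) and gave an adjusted p = 0.053 each with an estimated correlation, which was under 0.05 for both without anterior control replicate 1 or posterior tamoxifen replicate 2.

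Called members of other lists lay on both sides, and none of the lists counted in this paragraph passed camera with an estimated correlation. Among 17 Hedgehog pathway genes, 9 were higher and 4 lower in the anterior shelf (adjusted over the list alone, 9 and 4), including the targets Foxf1 at 3.78-fold and Foxd2 at 8.06-fold. Of 18 retinoic acid pathway genes 10 were higher and 3 lower (adjusted over the list alone, 10 and 3). Those higher anteriorly included the degrading enzymes Cyp26b1 (2.39-fold) and Cyp26c1 (5.96-fold). Of 34 BMP and TGF-beta genes, 7 were higher and 14 lower (adjusted over the list alone, 7 and 16), with Tgfb2 2.42-fold and Tgfbi 2.27-fold higher posteriorly. Among 36 Wnt genes 14 were higher and 8 lower (adjusted over the list alone, 18 and 10), and Wnt11 was 4.61-fold higher posteriorly. Fgfr4 was 5.47-fold and the cell cycle gene Ccnd1 2.26-fold higher posteriorly. Of 41 extracellular matrix genes, 3 were higher and 22 lower in the anterior shelf (adjusted over the list alone, 3 and 26), for instance the protease gene Adamts9 (3.10-fold) and the link protein gene Hapln1 (3.91-fold). Epithelial genes were higher anteriorly for 12 and lower for 1 of 21 members (adjusted over the list alone, 13 and 1). Krt14, a keratin of basal epithelial cells, was 2.66-fold higher. The adjusted p of camera was 0.56 for Hedgehog, 0.10 for retinoic acid, 0.48 for BMP and TGF-beta, 0.76 for Wnt, 0.56 for extracellular matrix and 0.55 for epithelial genes. With the preset correlation it was 0.055, 0.0055, 0.024, 0.15, 3.0e-06 and 5.2e-06. Of further lists, Six3 (16.4-fold), Pax3 (10.5-fold) and Hey1 (2.71-fold) were higher anteriorly, and Emx2 (13.4-fold), Nefm (4.08-fold) and Nefl (2.48-fold) posteriorly. Acta2 was 3.00-fold higher posteriorly, the 1 called member lower anteriorly in a smooth muscle and pericyte list with 5 of 11 higher. Neuronal genes had 2 higher and 6 lower among 16, Notch genes 8 and 3 among 22, and neural progenitor genes 3 and 2 among 9.

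Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3717 genes, 1634 higher and 2083 lower in the anterior shelf. Except for Bmp4, each gene named here for this comparison was called, with adjusted p between 1.9e-10 (Tnnt1) and 8.7e-05 (Mn1). Of all genes tested, 41.2% had no overlap between the 3 anterior and the 3 posterior values, where chance gives 10%. With the length and GC trend described below removed 4343 genes were called, 3118 of them among the 3717 in the same direction.

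The tamoxifen comparison in the anterior shelf asked how the treated tissue differs from controls. Genes of cholesterol biosynthesis and uptake moved mostly upward: of 24 members 14 rose, 3 fell and 7 gave no call (adjusted over the list alone, 15 rose and 3 fell). Stard4, a sterol transport protein, rose from 14.7 ± 1.25 to 35.1 ± 2.96 CPM (2.39-fold, n = 3 per group, adjusted p = 1.3e-06). The list passed camera with the preset correlation (adjusted p = 0.012) and had an adjusted p = 0.98 with an estimated correlation. In fatty acid synthesis and lipid storage, 9 of 15 genes rose and 1 fell (adjusted over the list alone, 9 and 1), among them the desaturase gene Scd1 at 1.88-fold. Its camera adjusted p was 0.16 with the preset and 0.98 with an estimated correlation, and with the length and GC trend described below removed 5 genes were higher and 2 lower.

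Among genes of palate patterning, Wnt5a, a ligand of the non-canonical Wnt pathway, rose from 138 ± 7.90 to 247 ± 3.59 CPM (1.79-fold, adjusted p = 1.1e-06). Its log2 fold change went from 0.84 to 0.27 with the trend removed (adjusted p = 0.0038). The mesenchymal homeobox gene Prrx1 rose 1.67-fold. Of 27 palatal shelf regulators, 12 rose and 7 fell (adjusted over the list alone, 12 and 9), and with the trend removed 7 were higher and 2 lower. In the tooth germ list 2 of 12 genes rose and 4 fell (adjusted over the list alone, 2 and 5), against 1 and 2 with the trend removed. Its falls included the homeobox genes Barx1, from 399 ± 39.1 to 239 ± 21.9 CPM, and Msx2, from 9.57 ± 1.45 to 5.42 ± 0.315 CPM. Bmp4 fell from 47.1 ± 5.70 to 35.8 ± 3.74 CPM (adjusted p = 0.0038). The largest falls under the naming rule were those of AA465934 (4.27-fold), Cbln1 (3.48-fold), Nrp (3.27-fold), Tgfbr3l (3.26-fold), Sp5 (3.01-fold) and Cited1 (2.83-fold), each called. Sp5 went from 25.6 ± 4.02 to 8.53 ± 2.43 CPM and Cited1, a transcriptional coregulator, from 24.5 ± 5.53 to 8.70 ± 1.47 CPM. Msx1, chosen after its values were seen, fell from 493 ± 111 to 218 ± 36.9 CPM (2.26-fold, adjusted p = 0.014).

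The largest rises were those of Gprin3 (8.05-fold), Cep85l (6.05-fold), the aminopeptidase gene Lnpep (5.54-fold), Zbed6 (5.39-fold), the phosphatase gene Ptpn4 (5.27-fold) and Zbtb37 (4.92-fold). Their log2 fold changes lay between 2.30 and 3.01, and between 1.42 and 2.31 with the trend removed. Zbed6 lies within an intron of another gene, so part of its count can come from that gene. The BMP and TGF-beta list had 14 rises and 9 falls among 34 genes (adjusted over the list alone, 15 and 10), and a camera adjusted p = 0.98, and 10 were higher and 4 lower without the trend. Its receptor genes Bmpr2 and Acvr2a rose 2.11-fold and 1.92-fold, and their log2 fold changes went from 1.07 and 0.94 to 0.23 and 0.40 without the trend, still called. In Hedgehog signalling 4 of 17 genes rose and 7 fell (adjusted over the list alone, 4 and 7), whereas 8 were higher and 3 lower without the trend. Its transcription factor gene Gli3 rose 1.65-fold and its co-receptor gene Cdon 1.68-fold, with log2 fold changes of 0.72 and 0.75 that went to 0.15 and 0.23. Of 21 FGF pathway genes 10 rose and 1 fell (adjusted over the list alone, 10 and 1), including the feedback inhibitors Il17rd (1.76-fold) and Spred2 (1.64-fold). The aryl hydrocarbon receptor gene Ahr rose 2.09-fold and the glutathione transferase gene Gstm1 fell 1.53-fold, within a xenobiotic response list of 6 rises and 3 falls among 21 (adjusted over the list alone, 6 and 3). Without the trend 9 FGF pathway genes were higher and 0 lower, and 4 and 1 xenobiotic response genes.

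Esr1, which encodes the main oestrogen receptor, was too low to be tested, at 0.130 ± 0.147 CPM in anterior controls and 0.174 ± 0.0171 CPM under tamoxifen. Esr2, at 0.724 ± 0.0944 and 0.978 ± 0.444 CPM, and Pgr, at 0.876 ± 0.0897 and 0.678 ± 0.15 CPM, gave no call (adjusted p = 0.48 each). Greb1, a gene induced by oestrogen in other tissues, rose 1.34-fold (adjusted p = 0.0039) and the nuclear receptor corepressor gene Nrip1 3.14-fold (adjusted p = 4.7e-05). Of the 20 oestrogen receptor and response genes tested, 4 rose and 6 fell, also when adjusted over the list alone, and 2 were higher and 1 lower with the length and GC trend removed.

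**Figure D3:**
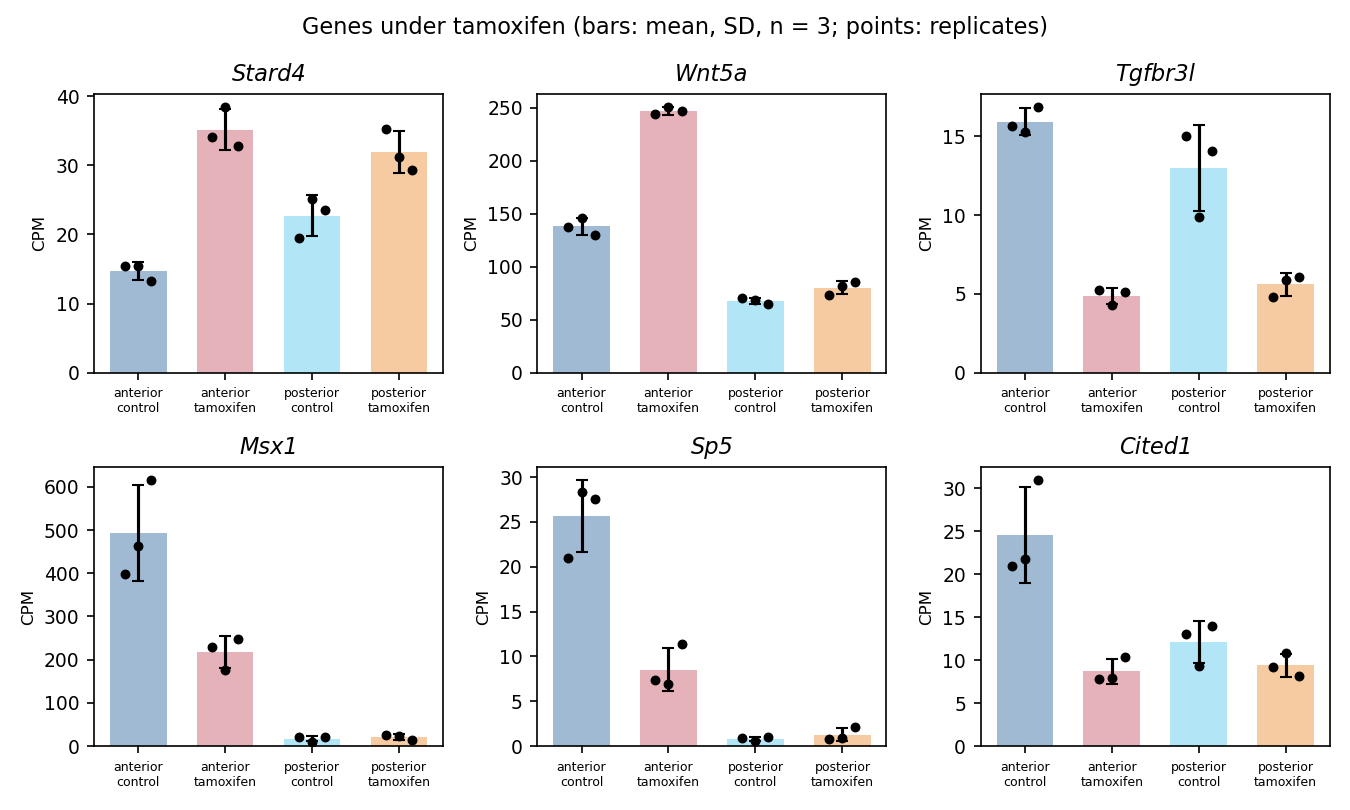
CPM (y axis, from 0) of 6 genes in the 4 groups (x axis), with bars for the mean, error bars for the SD over 3 libraries and a point per library. In the anterior shelf, Stard4 and Wnt5a are higher under tamoxifen (35.1 and 247 CPM on average) and Msx1, Sp5, Cited1 and Tgfbr3l lower (218, 8.53, 8.70 and 4.88 CPM).

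Cell cycle genes went both ways. Of 25 mitotic genes 9 rose and 8 fell (adjusted over the list alone, 13 and 9), with the kinetochore motor gene Cenpe up 1.55-fold and Birc5, which encodes survivin, down 1.4-fold. Without the trend 4 of the mitotic genes were higher and 7 lower. The cyclin gene Ccnd2 rose 1.77-fold. Markers of other cell types included epithelial genes (8 of 21 rose, 2 fell, and the same adjusted over the list alone) with Trp63 at 1.61-fold and Dsg2 at 2.12-fold, neuronal genes (5 of 16 rose, 0 fell, and 3 rose adjusted over the list alone) with Dcx at 2.22-fold and Map2 at 1.61-fold, and macrophage and other leukocyte genes (5 of 17 rose, 1 fell, and 4 and 1 adjusted over the list alone) with Mrc1 at 2.02-fold and Adgre1 at 1.96-fold. Of 23 skeletal muscle genes 1 rose and 6 fell (adjusted over the list alone, 0 and 5), including Tnnc1, from 1.43 ± 0.689 to 0.612 ± 0.0424 CPM, and Myl4, from 2.53 ± 0.388 to 1.63 ± 0.421 CPM. None of these 4 lists passed camera (adjusted p = 0.98 each with an estimated correlation, and 0.80, 0.57, 0.80 and 0.28 with the preset one), and 49.7% of all genes tested were called in this comparison. Their counts without the trend were 6, 3, 6 and 0 higher and 0, 0, 0 and 3 lower.

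Of 30 ribosomal protein genes 0 rose and 24 fell, also adjusted over the list alone (Rpl19 was 1.48-fold lower). Among 27 oxidative phosphorylation genes 0 rose and 20 fell (2 and 21 adjusted over the list alone), such as Ndufs7 (1.73-fold lower) and Ndufa4 (1.35-fold lower). Extracellular matrix genes showed 21 rises, 4 falls and 16 without a call among 41 (21 and 4 adjusted over the list alone), with Thbs1 at 1.64-fold and Loxl2 at 1.55-fold. With the preset correlation camera gave the ribosomal list an adjusted p = 3.9e-06, the oxidative phosphorylation list 0.00047 and the extracellular matrix list 0.083. With an estimated correlation each of the 3 had an adjusted p = 0.98. Across 12684 genes, the fold change in the anterior shelf had a Spearman correlation of 0.59 with transcript length and of -0.59 with GC content. The median log2 fold change was -0.32 in the shortest quartile of genes and 0.45 in the longest. The same correlation with length taken for each library against the mean of all libraries was -0.59 to -0.23 in the 6 controls and 0.35 to 0.47 in the 6 tamoxifen libraries (exact permutation test within regions, 2-sided, 400 arrangements, p = 0.005, the smallest it can give). If both parts came from the same embryos, which the labels do not say, fewer arrangements would be independent and this p would not hold. After removal of this trend, an alternative chosen after seeing the data, 4 ribosomal protein genes were higher and 9 lower, 4 and 7 oxidative phosphorylation genes, and 6 and 2 extracellular matrix genes.

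**Figure D4:**
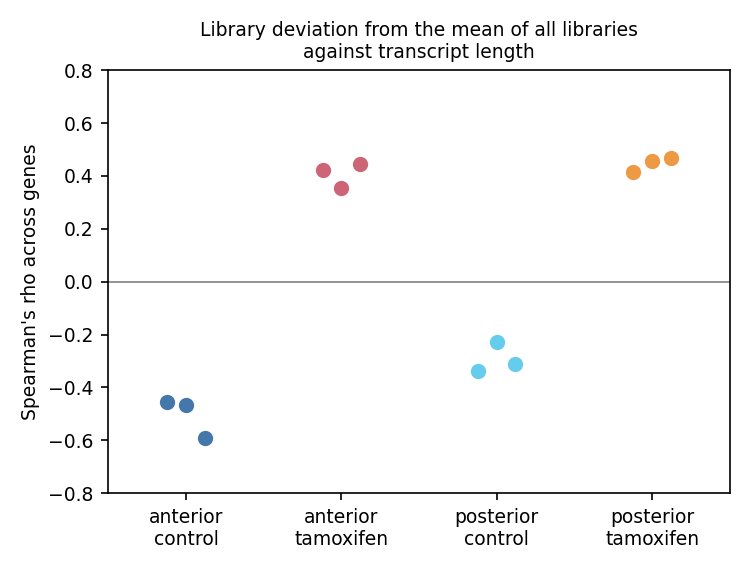
Spearman correlation across genes (y axis) between transcript length and each library's log2 CPM deviation from the mean of all libraries, with 1 point per library in the 4 groups (x axis). Controls lie between -0.59 and -0.23 and tamoxifen libraries between 0.35 and 0.47.

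In total, 7924 genes were called in the anterior shelf, 4089 higher and 3835 lower under tamoxifen, and no gene list passed camera with an estimated correlation (smallest adjusted p = 0.98, 1 list at unadjusted p under 0.05, 3 lists with the preset correlation and 10 by fry). No overlap between the 3 tamoxifen and the 3 control values was seen for 56.5% of the genes tested, where chance gives 10%. With the length and GC trend removed 5134 genes were called, 3352 of the 7924 in the same direction and 304 in the opposite direction. Of the genes named above and still called, the log2 fold changes of Ccnd2, Il17rd, Dcx and Ndufs7 went from 0.83, 0.82, 1.15 and -0.79 to 0.33, 0.32, 0.42 and -0.19. Those of Nrip1, Mrc1, Thbs1, Ahr, Dsg2, Scd1 and Stard4 went from 1.65, 1.01, 0.71, 1.07, 1.08, 0.91 and 1.26 to 0.98, 0.51, 0.38, 0.62, 0.65, 0.58 and 0.79, and those of Sp5 and Cited1 from -1.59 and -1.50 to -1.0 and -0.83. Removal of the trend ended the calls of Greb1, Prrx1, Barx1, Bmp4, Msx1, Cenpe, Rpl19, Gstm1, Tnnc1, Trp63 and Map2 (adjusted p between 0.057 and 0.86). Their log2 fold changes without the trend were 0.12, 0.13, -0.03, -0.15, -0.69, -0.07, -0.08, -0.24, -0.78, 0.20 and 0.23 in this order. Msx1 also lost its call without anterior control replicate 3 (adjusted p = 0.050) or anterior tamoxifen replicate 2 (adjusted p = 0.054), as Myl4 did without anterior control replicate 3 (0.062) or anterior tamoxifen replicate 1 (0.051).

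In the posterior shelf, the same comparison was made with separate libraries. The largest rises under the naming rule were those of Oasl2 (4.24-fold), Arfgef3 (3.19-fold), Igsf9b (3.19-fold), Tenm1 (2.93-fold), Lnpep (2.73-fold) and Lmbrd2 (2.68-fold). Oasl2, an interferon response gene, stood at 14.1, 2.83 and 2.65 CPM in posterior tamoxifen replicates 1, 2 and 3 and at 1.36 to 1.82 CPM in the controls (adjusted p = 0.047). Its log2 fold change of 2.08 went to 0.81 without posterior tamoxifen replicate 1. The call ended without that library, any of the 6 controls or anterior tamoxifen replicate 2 or 3 (adjusted p = 0.058 to 0.13), and with the trend removed (0.079). The log2 fold changes of the other 5 lay between 1.42 and 1.67, and between 0.94 and 1.23 with the trend removed. The largest falls were those of AA465934 (4.70-fold), Nrp (3.48-fold), Tgfbr3l (2.33-fold), Kcnq1ot1 (2.23-fold), Doc2g (2.04-fold) and the Wnt regulator gene Frat2 (2.01-fold). Lnpep rose from 8.79 ± 0.305 to 24.0 ± 2.47 CPM and Tgfbr3l fell from 13.0 ± 2.74 to 5.6 ± 0.707 CPM (n = 3 per group, adjusted p = 0.00055 and 0.00025). Kcnq1ot1 is a long non-coding RNA antisense to Kcnq1, and its counts cannot be separated from those of the overlapping gene.

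Of 11 smooth muscle and pericyte genes 4 rose, 0 fell and 7 gave no call in the posterior shelf (4 and 0 adjusted over the list alone), with Rgs5 from 5.82 ± 0.640 to 11.9 ± 2.49 CPM and Abcc9 from 5.86 ± 0.445 to 13.4 ± 4.38 CPM (log2 1.19, and 0.79 with the trend removed). The list passed camera with the preset correlation (adjusted p = 0.040) and had an adjusted p = 0.56 with an estimated correlation. Of 23 skeletal muscle genes 5 rose and 0 fell (adjusted over the list alone, 4 and 0), including the sarcomere gene Neb at 1.89-fold and Myl4 at 1.41-fold. Epithelial genes showed 9 rises and 0 falls among 21 (adjusted over the list alone, 10 and 0), including Trp63 (1.53-fold) and Dsg2 (1.88-fold). After trend removal 5 smooth muscle and pericyte, 5 skeletal muscle and 6 epithelial genes were higher and 0 lower.

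Among signalling genes, 14 of 34 BMP and TGF-beta genes rose and 1 fell (adjusted over the list alone, 14 and 2), with Acvr2a at 1.72-fold and Bmpr2 at 1.64-fold (log2 0.78 and 0.71, and 0.44 and 0.19 with the trend removed). Of 21 FGF pathway genes 8 rose and 0 fell (adjusted over the list alone, 9 and 0), with Il17rd at 1.42-fold and Spred2 at 1.44-fold. Both lists passed camera with the preset correlation (adjusted p = 0.040 each), and had an adjusted p = 0.56 each with an estimated correlation. Hedgehog genes gave 4 rises and 4 falls among 17 (adjusted over the list alone, 5 and 4), with Cdon at 1.68-fold and Gli3 at 1.46-fold. Of 27 palatal shelf regulators 8 rose and 2 fell (adjusted over the list alone, 9 and 2), with Prrx1 at 1.49-fold and Zeb1 at 1.39-fold. Other rises were those of the retinoic acid receptor gene Rarb (1.51-fold), the oxygen sensor gene Egln3 (1.55-fold), Adamts9 (1.51-fold) and Timp3 (1.35-fold). Counts higher and lower with the trend removed were 10 and 1 for BMP and TGF-beta, 7 and 0 for FGF, 5 and 5 for Hedgehog and 4 and 2 for the regulators. The log2 fold changes of Gli3, Prrx1, Adamts9, Cdon and Timp3 went from 0.55, 0.58, 0.60, 0.75 and 0.43 to 0.18, 0.19, 0.27, 0.41 and 0.21.

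In the cholesterol list 7 of 24 genes rose and 2 fell (adjusted over the list alone, 9 and 3), with Stard4 from 22.7 ± 2.95 to 31.9 ± 3.02 CPM and Sc5d 1.37-fold higher. Of 20 oestrogen receptor and response genes 4 rose and 0 fell (adjusted over the list alone, 6 and 2), with the growth factor gene Igf1 at 1.56-fold and its binding protein gene Igfbp5 at 1.36-fold. Esr1 averaged 0.144 ± 0.0944 CPM in controls and 0.159 ± 0.0321 CPM under tamoxifen and was not tested. Greb1 (adjusted p = 0.051), Esr2 (0.73) and Pgr (0.17) gave no call. Mitotic genes were lower for 8 and higher for 1 of 25 members (adjusted over the list alone, 8 and 2), including Cdca8 (1.31-fold lower) and Birc5 (1.32-fold lower). The stress response transcription factor gene Atf4 fell 1.45-fold. Once the trend was removed, 3 cholesterol and 3 oestrogen list genes were higher and 0 lower, and 0 mitotic genes were higher and 12 lower. The log2 fold changes of Igfbp5 and Atf4 went from 0.44 and -0.54 to 0.21 and -0.35.

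Ribosomal protein genes fell for 19 of 30 members with 0 rises (25 falls adjusted over the list alone), with Rpl19 and Rps19 both 1.30-fold lower, and oxidative phosphorylation genes for 15 of 27 with 0 rises (19 falls adjusted over the list alone), with Cox6c 1.25-fold and Uqcrh 1.26-fold lower. Of 41 extracellular matrix genes 10 rose and 0 fell, also adjusted over the list alone. The posterior fold change had a Spearman correlation of 0.56 with transcript length across genes, and of -0.48 with GC content. After the trend was removed, 0 ribosomal protein genes were higher and 8 lower, 0 and 6 oxidative phosphorylation genes, and 4 and 0 extracellular matrix genes.

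In total, 4625 genes were called in the posterior shelf, 2762 higher and 1863 lower, and 48.0% of the genes tested had no overlap between groups, where chance gives 10%. No list passed camera with an estimated correlation (smallest adjusted p = 0.56, 2 lists at unadjusted p under 0.05, 8 with the preset correlation and 13 by fry). With the trend removed 2814 genes were called, 1223 higher and 1591 lower, so that most calls were then lower. Of the 4625 genes, 1776 were still called in the same and 28 in the opposite direction. Zeb1, Il17rd, Rpl19, Uqcrh, Igf1, Stard4, Sc5d, Trp63 and Neb lost their calls (adjusted p between 0.065 and 0.25), with log2 fold changes of 0.16, 0.18, -0.10, -0.14, 0.26, 0.19, 0.18, 0.29 and 0.38. The count fell to 2714, 2830 and 3045 without posterior control replicate 1, posterior control replicate 3 and posterior tamoxifen replicate 1, and Myl4 lost its call without posterior control replicate 2 (adjusted p = 0.053) or 3 (0.064) and without posterior tamoxifen replicate 1 (0.078) or 2 (0.085).

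Changes in the 2 parts of the shelf overlapped. Of the genes called in both comparisons, which share no library, 2451 were higher in both (707.7 expected for independent lists), 1703 were lower in both (447.7 expected) and 15 went in opposite directions (1141 expected). The labels do not say whether both parts came from the same embryos, so the libraries, and the expected counts, may not be independent. Across the 15958 genes the log2 fold changes had a Pearson correlation of 0.64 and a Spearman correlation of 0.74, given as a description because genes are not independent replicates. Tgfbr3l, Nrp, AA465934 and Lnpep were among the largest changes in both parts. With the length and GC trend removed, 2212 genes were called in the same direction (453.6 expected) and 11 in opposite directions. Of the 2212, 914 were higher and 1298 lower in both parts, so the balance between rises and falls turned round. That balance also depended on scaling. With scaling to the upper quartile and the trend kept, anterior calls were 3824 higher and 4195 lower, and posterior calls 2483 and 2233. With RLE size factors, another scaling, they were 4131 and 3779, and 2689 and 1922.

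Whether the effect of tamoxifen differed between the parts was tested as an interaction. The smallest p belonged to Wnt5a, whose rise was larger in the anterior shelf by 0.60 on the log2 scale (SE 0.10, adjusted p = 0.081), and by 0.40 with the trend removed (adjusted p = 0.14). Stard4 (difference 0.76, adjusted p = 0.16) and the Hedgehog receptor gene Ptch1 (0.68, 0.17) lay in the same direction. On the other side were Hey1 (-0.70, 0.13), the ciliated epithelium gene Tppp3 (-1.18, 0.15), Myl4 (-1.15, 0.17) and Acta2 (-0.95, 0.18), and, chosen after their values were seen, Sp5 (-2.23, 0.18) and Msx1 (-1.50, 0.29). In the posterior shelf Msx1 stood at 16.8 ± 6.14 and 21 ± 6.77 CPM, Sp5 at 0.802 ± 0.224 and 1.28 ± 0.750 CPM and Cited1 at 12.1 ± 2.44 and 9.38 ± 1.36 CPM in controls and under tamoxifen, with no call (adjusted p = 0.52, 0.23 and 0.14). Of 23 skeletal muscle genes, 0 were called over all genes and 10 had a lower effect in the anterior shelf when adjusted over the list alone. The corresponding counts were 8 of 24 for a higher effect in the cholesterol list and 4 of 11 and 4 of 12 for a lower effect in the smooth muscle and pericyte and the tooth germ lists. These 4 lists passed camera with the preset correlation (adjusted p = 1.6e-05, 8.3e-05, 0.0024 and 0.00052), and had an adjusted p = 0.43, 0.43, 0.31 and 0.15 with an estimated correlation. By fry the tooth germ list passed (adjusted p = 0.015) and the other 3 did not.

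edgeR's quasi-likelihood test called 0 genes for the interaction, limma-voom 0 and DESeq2 179, among them each gene given a difference here except Msx1. At unadjusted p under 0.05 there were 2110 genes, where 797.9 would be expected by chance, and 1729 with the length and GC trend removed. The difference of the effects itself had a Spearman correlation of 0.46 with transcript length and of -0.53 with GC content, which together accounted for 33.2% of its variance. The lists called with an estimated correlation numbered 0 (smallest adjusted p = 0.15, 5 at unadjusted p under 0.05, 9 with the preset correlation, 2 by fry), so a gene called in only 1 part of the shelf is not shown to respond differently there.

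The regional division was also measured within the tamoxifen-treated embryos. Shox2 stood at 453 ± 110 CPM anteriorly and 18.1 ± 5.14 CPM posteriorly (25-fold, n = 3 per group), Alx1 was 31.8-fold, Six3 25.1-fold, Pax3 14.6-fold and Msx1 10.4-fold higher in the anterior shelf. Meox2 was 14.7-fold, Tbx22 5.97-fold, Barx1 3.10-fold and Mn1 1.54-fold higher posteriorly. Fgf10 was 2.71-fold and Inhba 4.05-fold higher anteriorly, while Bmp4, at 35.8 ± 3.74 and 39.4 ± 2.44 CPM, gave no call (adjusted p = 0.40). Wnt5a was 3.08-fold higher in the anterior shelf, and Wnt11 5.94-fold, Fgfr4 9.71-fold, Msx2 5.66-fold, the retinoid receptor gene Rxrg 9.13-fold and the cell cycle inhibitor gene Cdkn1a 3.58-fold higher in the posterior shelf.

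Of the 12 anterior palate genes 9 were higher anteriorly and 0 lower, also adjusted over the list alone (camera adjusted p = 0.015), and all 12 posterior palate genes were lower anteriorly (0.012). Skeletal muscle genes were lower anteriorly for 22 of 23 members, also adjusted over the list alone (camera 0.033), with Tnnt1 at 2.53 ± 0.575 against 71.2 ± 10.3 CPM and Tnni1 at 0.386 ± 0.169 against 48.2 ± 4.40 CPM. Cartilage genes were lower for 14 of 17 (16 adjusted over the list alone, camera 0.033), with Col2a1 5.19-fold and Col9a3 3.33-fold higher posteriorly. Other members of lists were Foxf1 (2.59-fold), Cyp26b1 (2.62-fold) and Trp63 (1.97-fold), higher anteriorly, and Acta2 (5.80-fold), Emx2 (25.7-fold), Igf1 (1.97-fold), Nefm (3.52-fold) and Nefl (2.81-fold), higher posteriorly. In all, 2846 genes were called, 1213 higher and 1633 lower in the anterior shelf, and 33.1% of the genes tested had no overlap between the groups, where chance gives 10%. With the length and GC trend removed 3730 genes were called, 2765 of them among the 2846 in the same direction, and the muscle list had an adjusted p = 0.053. Muscle and cartilage lists lost their call without anterior control replicate 2 (adjusted p = 0.057 and 0.064), anterior tamoxifen replicate 3 (0.056 and 0.087) or posterior control replicate 2 (0.052 each). The cartilage list also lost its call without posterior tamoxifen replicate 3 (0.050) or with the replicate number as a block (0.099).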

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

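Removal of the length and GC trend, alone or with the replicate block, division of counts by 2 and thinning were chosen after seeing the data. Across 179 pairs of gene and comparison, 4367 of 4459 alternatives kept direction and side of the threshold, 65 lost a call, 22 gained one and 5 changed sign. Of the lost calls, 20 came with the trend removed and 21 with the trend removed and the block. The naming rule favours called genes without overlap, so these counts do not describe all genes. Over all genes, 42.3% of anterior and 38.4% of posterior tamoxifen calls were kept with the trend removed. With the trend removed, tamoxifen calls numbered 5134 in the anterior and 2814 in the posterior palate, and 2212 genes were called in the same direction in both. With the trend removed and the replicate number as a block, they numbered 4989 and 2657, and 1 gene was called for the interaction. With the block alone, 0 gene lists were called for region in controls, where the anterior and posterior palate lists were called without it (adjusted p = 0.060 each with it), the cartilage list lost its call under tamoxifen (0.099), and gene counts were 7800, 4561, 0, 3711 and 2811 for tamoxifen in anterior and posterior palate, interaction, and region in controls and under tamoxifen. The cause was not tested.

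At an adjusted p under 0.01 there were 2215 calls for tamoxifen in posterior palate, 2194 for region in controls and 1839 for region under tamoxifen. With an absolute log2 fold change of at least 1 there were 861 and 285 calls for tamoxifen in anterior and posterior palate, and 1182 and 1079 for region in controls and under tamoxifen. These thresholds are stricter by construction. For the interaction, DESeq2 called 179 genes and the embryo sex covariate gave 1, and the cause was not tested. Lists called by camera with the preset correlation numbered 3, 8, 9, 13 and 14 for tamoxifen in anterior palate, in posterior palate, the interaction, region in controls and region under tamoxifen, and by fry 10, 13, 2, 19 and 21. fry does not compare a list with other genes.

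Leaving out 1 library gave 6553 to 7961 calls for tamoxifen in anterior palate, 2714 to 5485 in posterior palate, 0 to 6 for the interaction, 2483 to 4342 for region in controls and 2090 to 3089 for region under tamoxifen. The posterior tamoxifen count moved by over 1.5 times without con_PP replicate 1 (2714), con_PP replicate 3 (2830) or TAM_PP replicate 1 (3045). Interaction calls appeared without TAM_AP replicate 2 (3), TAM_AP replicate 3 (6), con_PP replicate 1 (1) or TAM_PP replicate 3 (1). Lists called ranged from 0 to 0 for both tamoxifen comparisons and the interaction, from 2 to 5 for region in controls (5 without con_AP replicate 1, 4 without TAM_PP replicate 2) and from 2 to 4 for region under tamoxifen (2 without con_AP replicate 2, TAM_AP replicate 3 or con_PP replicate 2). The cause was not tested, apart from the fewer samples.

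Signs changed for Cenpe under tamoxifen in anterior palate with the trend removed (-0.072, and -0.072 with the block), for Bmp4 between regions in controls (-0.0081, and -0.010 with the block), and for Esr2 under tamoxifen in posterior palate without TAM_PP replicate 3 (0.20, within a leave-one-out range from -0.70). None was called under those settings, and the cause was not tested. Greb1 in posterior palate gained a call with DESeq2 (adjusted p = 0.037), and without TAM_AP replicate 2 or TAM_PP replicate 1 (0.039 and 0.034), within a leave-one-out range up to 0.18. Alternatives intended for normalized values (pseudocount 0.1, quantile normalization, scaling of values to the upper quartile, filters on values) were not run, since the files hold counts.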

Other observations

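The gene lists of this part, apart from those fixed beforehand, and the tests on the length and GC trend, on total counts, on a batch that coincides with treatment and on posterior tissue were chosen after the result was seen. The camera p-values of lists chosen in this way come from the data that led to the choice, so they are a description only. Of 39 imprinted genes, expressed from the copy of 1 parent, 17 were lower and 0 higher in the anterior than in the posterior palate in controls, and 14 and 0 under tamoxifen. Skeletal muscle and cartilage genes were also lower there (22 of 23 and 14 of 17 in both), and whether the content of these tissues accounts for the imprinted genes was not tested. The unadjusted p of camera with an estimated correlation was 0.0028 in controls and 0.0019 under tamoxifen. In controls Igf2 stood at 2887 CPM anteriorly and 4337 CPM posteriorly (log2 fold change -0.59, adjusted p = 3.0e-05), and H19 (-0.52), Dlk1 (-1.36) and Ndn (-0.64) were also called lower, all chosen after their values were seen. Host transcripts of small nucleolar RNAs fell under tamoxifen for 13 of 17 members in the anterior and 10 of 17 in the posterior palate with 0 rises (camera unadjusted p = 0.020 and 0.0090). After removal of the length and GC trend 8 and 7 of 15 fell. Gas5, chosen after its values were seen, fell 1.5-fold and 1.32-fold. Of 28 transcripts known to be kept in the nucleus with unspliced introns, 2 were higher and 11 lower in the anterior and 0 and 8 in the posterior palate. With the trend removed these counts were 0 and 20 in the anterior and 0 and 19 in the posterior palate (camera unadjusted p = 0.065 and 0.049). Of 10 nuclear long non-coding RNAs, 1 was higher and 5 lower in the anterior and 1 and 3 in the posterior palate. With the trend removed these counts were 0 and 7 in the anterior and 0 and 6 in the posterior palate (camera unadjusted p = 0.0017 and 0.0040). Whether nuclear and unspliced transcripts follow a trend fitted over genes of all kinds was not tested. The falls added for these lists therefore cannot be told apart from an effect of the removal itself.

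Interferon response genes stood out in 2 libraries. Over 20 genes, the median log2 level above controls was 1.52 in TAM_AP replicate 1 and 2.20 in TAM_PP replicate 1, with 16 and 15 genes at least 2-fold higher, and between -0.10 and 0.40 in the other 10 libraries. Usp18 reached 5.74 and 8.30 CPM in these libraries and 0.595 to 1.22 CPM in the others, and Bst2 30.8 and 34.8 against 6.25 to 10.5 CPM. The histocompatibility gene H2-D1 was lower in the same libraries, at 2.22 and 2.31 against 3.98 to 7.09 CPM. The list was not called by camera (unadjusted p = 0.52 and 0.44 for tamoxifen in anterior and posterior palate), and no explanation was tested.

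The fold changes under tamoxifen followed transcript length and GC content in both parts of the palate. After removal of the trend, 42.3% of anterior and 38.4% of posterior calls were still made in the same direction (304 and 28 genes were called in the opposite direction). This argues against the trend as fitted here as the whole cause of the calls. Length and GC content came from 1 transcript per symbol in another genome build. Calls left by an incomplete removal therefore cannot be told apart from other changes. In the shared range of total counts, 44.4 to 48.8 M, lay 2 control and 4 tamoxifen libraries. There every tamoxifen library lay above both controls in its correlation with length, by a gap of 0.666 (SD within groups 0.0553). Both controls were posterior, so for the posterior palate this argues against a difference in total counts. Anterior totals ran from 39.4 to 43.3 M in controls and from 44.4 to 73.0 M under tamoxifen. No anterior libraries of both treatments share a total, but the correlation did not rise with total counts within the anterior groups. It was -0.46 at 39.4 M and -0.59 at 43.3 M in controls, and 0.45 at 44.6 M and 0.42 at 73.0 M under tamoxifen. Posterior controls at 48.2 and 48.8 M lay at -0.34 and -0.31. These values argue against total counts as the cause in the anterior palate too. A library or RNA batch that coincides with treatment cannot be told apart from tamoxifen, since every tamoxifen library lay above every control library in its correlation with length, by a gap of 0.581, and the labels give no batch. Both an effect of the drug and a difference in RNA handling may therefore underlie the trend. It also ran between the untreated parts. In controls the anterior against posterior fold change had a Spearman correlation of -0.36 with transcript length and of 0.24 with GC content. The correlation of each control library with length was -0.59 to -0.46 in the anterior and -0.34 to -0.23 in the posterior palate. The cause of this regional difference was not tested.

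Higher cholesterol biosynthesis and uptake genes under tamoxifen in the anterior palate were not removed with the trend, after which 17 of 24 members were called higher. No single anterior library carried the pattern, since the fewest members called higher without 1 of the 6 anterior libraries was 12 (without TAM_AP replicate 1). An effect of tamoxifen on sterol synthesis may underlie the rise, but a batch that coincides with treatment remains open, and camera with an estimated correlation did not call the list.

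Msx1, Sp5 and Cited1 were lower under tamoxifen in the anterior palate. More posterior tissue in the treated samples would have to reach 57.7% to explain Msx1, and would raise 26 posterior and muscle genes to a median log2 fold change of 4.01, whereas their median was -0.37 (SD 0.90) and 0 of them reached the prediction. This prediction took the added tissue to have the composition of the posterior control samples. Other differences in dissection were not tested. For Sp5 and Cited1 the length and GC trend as fitted here is argued against by the weaker log2 fold change after removal, -0.83, still called. For Msx1 the trend cannot be told apart from a change. Its log2 fold change went from -1.18 (SE 0.32) to -0.69 (SE 0.29, adjusted p = 0.10). Cited1 also shrank, from -1.50 (SE 0.18) to -0.83 (SE 0.13), and stayed called. The loss of the call for Msx1 therefore goes with its larger error, and does not set its shrinkage apart from that of Cited1. A response of these anterior genes to tamoxifen may remain, and a batch is open here too.

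Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05, and 1 of the 10, the real one, gave as many calls in each comparison of genes. The real counts and the highest of the other splits were 7924 and 0 for tamoxifen in anterior palate, 4625 and 2 in posterior palate, 3717 and 0 for region in controls, and 2846 and 0 for region under tamoxifen. For gene lists, 10 of 10 splits gave as many as the real 0 in both tamoxifen comparisons (highest other 0), and 1 of 10 for region, with 2 lists and 0 elsewhere in controls and 4 lists and 1 elsewhere under tamoxifen. For the interaction the real counts were 0 genes and 0 lists, which every split reaches (100 of 100), so the splits decide nothing, and the highest of the others was 6230 genes and 1 list. The same holds for the lists in both tamoxifen comparisons. The 4 splits that kept the anterior labels and exchanged 4 of the 6 posterior ones called 1978 to 6230 genes for the interaction. The other 95 called 0 genes. Such an exchange puts mostly tamoxifen libraries in the posterior control group, so a change shared by both parts counts as a difference. Those 4 counts are therefore no reference for chance.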
